A study of Homo sapiens with 4 samples.

How the data were processed

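Small RNA was sequenced from MIA PaCa-2 cells, an established cell line from a human pancreatic carcinoma, at 0, 6, 24 and 48 h of treatment with 1 µM sotorasib. Sotorasib is a covalent small-molecule cancer drug. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the QIAseq miRNA Library Kit. The labels give 1 library per time, so the 4 libraries are 4 groups of 1 and there is no replicate at any time. None of them is an untreated library at 6, 24 or 48 h.

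The authors deposited 1 workbook of mature miRNA values. Its sheets hold normalized log2 values for 2632 miRNAs in the 4 libraries, the authors' log2 fold changes of 6, 24 and 48 h against 0 h, and 6 lists of miRNAs that passed 1.5-fold up or down. Per the workbook's description sheet, the authors normalized by TMM (trimmed mean of M values, a factor per library that assumes most miRNAs do not change) and took log2. The 3 full sheets held identical normalized values. Per the submitters' processing notes, the genome build was hg38 and the tools included bcl2fastq 2.15.0, FastQC 0.11.9 and MultiQC 1.14. The aligner, the counter and the use of the kit's molecular identifiers are not given in the sources used here. The column names carry a sample prefix that differs from the sample titles, so columns were matched by the time they name.

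The deposited log2 values were turned back to normalized reads-per-million (RPM). No value lay below 0, and a miRNA under 1 RPM was listed at 0, which hides up to 4, 4, 3 and 1 reads at 0, 6, 24 and 48 h. Low values were whole multiples of 1 step per library, 0.227, 0.235, 0.291 and 0.513 RPM at 0, 6, 24 and 48 h. Dividing by this step recovered read numbers that were whole within 0.05 read for 100% of values of up to 1000 reads and for 99.2 to 99.8% of all values above 0, depending on the library. The recovered totals were 4509897, 4389085, 3410843 and 1863242 reads, and the TMM factors they imply were 0.976, 0.971, 1.01 and 1.05. Totals leave out the reads of miRNAs listed at 0. The fixed design had allowed for raw counts. Since the workbook holds normalized values, the form written for that case was used: the authors' values on a linear scale with a pseudocount of 1 RPM.

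A miRNA was compared where its mean over the 4 libraries was at least 10 RPM, which left 373 miRNAs with 99.9% of the recovered reads. The log2 ratio was taken as log2(value + 1) at 6, 24 or 48 h minus that at 0 h, which understates the change of low miRNAs. A miRNA was called higher or lower where this ratio passed 1.5-fold. This is a rule of size and not a test: with 1 library per time, no p-value was computed and no difference has a replicate check. Folds of single miRNAs are ratios of the normalized values without a pseudocount, with exact conditional 95% intervals from the recovered reads. Where a miRNA was listed at 0 in 1 library of the pair, the fold is a lower bound against a floor of 1 RPM or 3 reads, whichever was greater (1.54 RPM at 48 h). Such a bound holds for the listed values: it leaves out the counting error of the other library and is no 95% limit. Intervals cover counting error only, since sequenced reads may be copies of the same molecule and culture and library preparation add spread that these libraries cannot show.

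Before the data were examined, 26 lists of miRNAs were fixed (families, genomic clusters, MAPK-linked miRNAs, markers of other tissues, and entries whose sequence matches other RNA classes), matched on the name without the arm. Both arms counted as members. A list with at least 3 members above the floor was described by its median log2 ratio, set beside the central 95% of medians of 10000 random lists of the same size matched on mean abundance. This describes these libraries and is no test of replication. The named miRNAs were also fixed by rule beforehand: the 10 highest and 10 lowest ratios at each time, the 10 most abundant miRNAs, and up to 3 of the most abundant members of each list. The following miRNAs fall outside this rule and were named after their values were seen: let-7c-5p, miR-16-1-3p, miR-18a-5p, miR-20a-5p, miR-21-3p, miR-23a-5p, miR-132-3p, miR-146a-5p, miR-181b-2-3p, miR-301a-3p, miR-320a-3p, miR-320b, miR-328-3p, miR-339-5p, miR-497-5p, miR-503-5p, miR-874-3p, miR-449b-5p and miR-449c-5p. The same holds for miR-221-5p, and for miR-20a-3p and miR-25-5p, which are shown in a figure only.

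Calls at 6, 24 and 48 h share the single 0 h library. Their overlap was set beside that of independent lists and beside 1000 simulated draws of unchanged libraries against the same 0 h library, once with counting error alone and once with an added log2 spread of 0.14. This spread per library was estimated from the median absolute deviation of the 6 h against 0 h ratios, so it is no replicate noise level. The order of levels over time was set beside the share that 4 exchangeable values would give. Alternatives fixed beforehand were scaling by total reads, by median-of-ratios size factors or to the median ratio, the authors' log2 ratios, floors of 1 and 100 RPM and no floor, pseudocounts of 0.1 and 10, a 2-fold rule, the more abundant arm of each miRNA alone, and calls whose counting interval excludes 1. Thinning to the 48 h depth, leaving out entries that match other RNA classes, and ordering without the 48 h library were chosen after seeing the data.

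The procedure was tested on simulated data with 200 changed miRNAs among the 373, drawn at the real depths with counting error and the same added spread, to which its rates are tied. For 48 h against 0 h it recovered 94% of 2-fold higher and 90% of 2-fold lower miRNAs, 100% of 3-fold higher and 98% of 3-fold lower ones, and 4.05% of unchanged miRNAs passed 1.5-fold. Positions of precursors come from GENCODE release 29 on GRCh38, and from RefSeq on the same assembly where GENCODE lacked the gene. All 373 miRNAs had a position, and 371 had a GC content, for 325 that of the side of the precursor that holds the arm and for 46 named without an arm that of the whole precursor. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.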

Results

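MicroRNAs of MIA PaCa-2 pancreatic cancer cells were profiled over 48 h of treatment with 1 µM sotorasib, a covalent small-molecule cancer drug, at increasing times of exposure. No cells left untreated for 6, 24 or 48 h were sequenced, so treatment and time in culture cannot be told apart. One library was sequenced at each of 0, 6, 24 and 48 h, so no value has a replicate and all intervals are 95% intervals for counting error only. The recovered depth was 4509897, 4389085 and 3410843 reads at 0, 6 and 24 h and 1863242 reads at 48 h. Of 2632 mature miRNAs, 751, 730, 735 and 802 were listed above 0 at these times. Levels are the authors' TMM-normalized reads-per-million (RPM). Comparisons cover the 373 miRNAs with a mean of at least 10 RPM, and "higher" or "lower" means past 1.5-fold on the log2(value + 1) scale.

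The miRNAs that make up most of the libraries stayed within 1.5-fold at every time. The most abundant was miR-16-5p, at 10.8% of reads at 0 h (Wilson 95% interval 10.7 to 10.8) and 13.0% at 48 h (12.9 to 13.0). The oncogenic miR-21-5p was at 83314 RPM at 0 h and 71871 at 48 h. The tumour-suppressive let-7a-5p and let-7i-5p were at 58364 and 81002 RPM at 0 h and 60974 and 70115 at 48 h. The remaining miRNAs of the 10 most abundant, miR-93-5p, let-7f-5p, miR-29a-3p, miR-7-5p, miR-25-3p and miR-191-5p, also stayed within 1.5-fold, the greatest difference being that of miR-29a-3p at 48 h, 1.40-fold lower (1.39 to 1.41).

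At 6 h few miRNAs differed from 0 h, and the 3 lowest ratios were those of minor arms, the less abundant strands of their precursors. The strand miR-222-5p was 2.73-fold lower (2.48 to 3.01), at 372.2 RPM at 0 h and 136.3 at 6 h, while the other strand, miR-222-3p, a repressor of the cell cycle inhibitor CDKN1B, was at 1292 and 1286. The strand miR-29b-1-5p was 2.27-fold lower (1.98 to 2.61), and miR-26b-3p was 2.02-fold lower (1.59 to 2.59). In all, 8 miRNAs were higher and 7 lower at 6 h, or 15 of the 373. The other 4 lower miRNAs were miR-19b-1-5p, miR-12136, miR-26a-1-3p and miR-30c-2-3p. The higher ones were miR-30c-1-3p, at 39.5 RPM at 0 h and 71.5 at 6 h, and miR-129-5p, miR-1292-5p, miR-345-3p, miR-1275, miR-128-1-5p, miR-296-3p and miR-5701. The counting intervals of miR-296-3p and miR-5701 included 1.

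Among the fixed lists at 6 h, the median log2 ratio of the MAPK, AP-1 and CREB linked miRNAs was -0.14, with 10 of 10 members below 0 and 1, miR-222-5p, past 1.5-fold; random lists of like abundance spanned -0.14 to 0.15. Taken over the more abundant arms alone, the median lay inside the random lists (-0.16 to 0.18). The miR-17~92 cluster and its paralogs, a MYC-driven group that promotes proliferation, had a median of -0.18 over 17 members (random lists -0.10 to 0.10), with 1 lower, while the sum of its levels was 1.08-fold higher (1.08 to 1.09), with miR-93-5p at 59652 RPM at 0 h and 67648 at 6 h. The miR-26 family had a median of -0.21 over 5 members (random lists -0.21 to 0.21), with 2 lower. With no floor on abundance this median lay inside its random lists (-0.22 to 0.21). The neuronal markers had a median of 0.21 over 5 members (random lists -0.18 to 0.19), with 1 higher, miR-128-1-5p. It was 0.04, inside the random lists (-0.20 to 0.18), over the more abundant arms alone. Without a floor on abundance, 79 miRNAs were higher and 100 lower at 6 h, and with a pseudocount of 10 only 1 of the higher calls was left, so the counts at 6 h rest on the choice of floor and pseudocount.

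At 24 h miR-222-5p was at 14.5 RPM, 25.6-fold lower than at 0 h (19.3 to 34.7), and miR-222-3p was at 1267. The precursor gene MIR222 lies on the minus strand of chromosome X at 45747015 to 45747124 (GRCh38), in an intron of MIR222HG. MIR221 also lies in an intron of MIR222HG, and its minor arm miR-221-5p stayed within 1.5-fold at every time. It was at 195.9 RPM at 0 h, 197.9 at 24 h and 161 at 48 h. The abundant entry miR-12135 was at 2987 RPM at 0 h and 456.6 at 24 h, 6.54-fold lower (6.21 to 6.90). Its position on chromosome 15, 73299910 to 73299979, falls in an intron of NEO1. The strand of miR-12135 was not available here, so it may differ from that of NEO1. Other low values were those of miR-7974, 8.43-fold lower (4.87 to 15.8), miR-573, 5.73-fold lower (3.62 to 9.53), and miR-130a-5p, 5.40-fold lower (2.85 to 11.3). In the opposite direction, miR-449a, a miRNA of the miR-34 seed family that restrains cell cycle genes, was at 28.9 RPM at 0 h and 164.8 at 24 h, 5.71-fold higher (4.70 to 6.98). Its gene MIR449A lies in an intron of CDC20B on chromosome 5 at 55170532 to 55170622. In all, 46 miRNAs were higher and 44 lower.

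Other miRNAs with the highest ratios at 24 h were of low abundance at 0 h. The levels of miR-345-3p were 8.18 RPM at 0 h and 60.2 at 24 h, 7.35-fold higher (5.14 to 10.8). Those of miR-296-3p were 6.91-fold higher (3.95 to 12.9), those of miR-129-5p 5.72-fold (3.45 to 9.97), those of miR-874-5p 5.57-fold (3.67 to 8.73) and those of miR-195-3p 3.85-fold (3.09 to 4.83). The entry miR-1224-5p was listed at 0 at 0 and 6 h and was at 8.72 RPM at 24 h, at least 8.72-fold higher, and miR-4516 was at least 6.39-fold higher.

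The miR-17~92 cluster and its paralogs had 9 of 17 members lower and 0 higher at 24 h. Their median log2 ratio was -0.59, with random lists at -0.22 to 0.20. Members included miR-20a-5p, at 7519 RPM at 0 h and 4789 at 24 h, and miR-18a-5p, 1.61-fold lower (1.51 to 1.72), while miR-93-5p, the most abundant member, was at 59652 and 62057. The family of miR-192, miR-194 and miR-215, expressed in gut epithelium, had a median of 0.57 (random lists -0.46 to 0.56), with 2 of 4 members higher and miR-192-5p at 1536 and 2164 RPM. This median was 0.49, inside the random lists (-0.54 to 0.54), with the more abundant arms alone. The miR-29 family, repressors of collagen genes, had 3 of 7 members lower, with miR-29b-3p at 23220 and 13870 RPM, and its median of -0.28 lay inside the range of random lists. The 8 entries whose sequence also matches tRNA, rRNA or snRNA had a median above their random lists (-0.34 to 0.49), with 6 higher and 0 lower. Of these, miR-7977 was 2.03-fold higher (1.83 to 2.25), miR-1246 1.60-fold (1.23 to 2.08) and miR-4485-3p 4.24-fold (2.51 to 7.50). Reads of such entries may come from the other RNA class.

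At 48 h the strand miR-27a-5p was 72.6-fold lower than at 0 h (35.1 to 181), at 260.4 RPM at 0 h, 292.4 at 24 h and 3.59 at 48 h (7 reads), while miR-27a-3p was at 9492 at 0 h and 10351 at 48 h. The precursor gene MIR27A lies on the minus strand of chromosome 19 at 13836440 to 13836517. The strand miR-222-5p was 40.3-fold lower (25.4 to 68.2) and miR-12135 8.68-fold lower (8.03 to 9.40). Another group, miR-573, miR-7974 and miR-3662, in introns of DHX15, ZNF653 and HBS1L, was listed at 0 at 48 h, at least 22.8-fold, 22.3-fold and 19.2-fold lower. The 3 reads of miR-1275 at 48 h put it 57.8-fold lower (19.6 to 281). In all, 50 miRNAs were higher and 91 lower. The median log2 ratio of all 373 at 48 h was -0.13, so part of this balance depends on the scaling: relative to that median the split was 68 higher and 78 lower, with scaling by total reads 64 and 80, and with median-of-ratios size factors 75 and 75. The authors' deposited table listed 172 up and 227 down at 48 h, of which 121 and 134 lay below the floor used here.

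The highest ratios at 48 h were those of miR-1224-5p, at least 51.3-fold higher, miR-4516, at least 39.5-fold higher, and miR-5701, 49.3-fold higher (22.0 to 137), from 6 reads at 0 h. The entries miR-320d and miR-320c were 18.1-fold (15.2 to 21.7) and 10.7-fold higher (9.53 to 12.1), at 31.8 and 74.3 RPM at 0 h and 575.3 and 798.3 at 48 h. Their near-identical relatives were at 1412 RPM at 0 h and 1542 at 48 h (miR-320a-3p) and 1.59-fold higher (miR-320b, 1.21 to 2.09). The genes of miR-320c lie on chromosome 18 at 21683510 to 21683597 and 24321686 to 24321735, and those of miR-320d on chromosomes 13 and X. The authors' counting could split reads between these copies, so the single values are uncertain. The cell cycle regulator miR-449a remained high at 195.4 RPM, 6.77-fold higher (5.52 to 8.34), and miR-877-5p was 4.72-fold higher (3.81 to 5.87). Of the entries that match other RNA classes, 5 of 8 were higher and 1 lower, with a median of 1.70 (random lists -0.78 to 0.40), or 1.83 relative to all miRNAs.

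The miR-17~92 cluster and its paralogs had 12 of 17 members lower and 0 higher at 48 h, with a median of -0.83 (random lists -0.39 to 0.27), or -0.70 relative to all miRNAs. The levels of miR-20a-5p were 7519 RPM at 0 h and 3946 at 48 h, 1.91-fold lower (1.86 to 1.95), those of miR-18a-5p 2.17-fold lower (1.98 to 2.37) and those of miR-19b-1-5p 11.5-fold lower (4.37 to 43.1). Of the 3 most abundant members, miR-93-5p was at 59652 and 59365 and miR-25-3p at 28245 and 26551 RPM, while miR-19b-3p was 1.56-fold lower (1.53 to 1.59), which is not past 1.5-fold relative to all miRNAs. The gene MIR20A lies in an exon of MIR17HG on chromosome 13 at 91351065 to 91351135. Sequences of this family are close to each other, so reads may be split between members. With the more abundant arm of each miRNA alone, the median was -0.68 over 10 members, still outside its random lists.

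The miR-26 family had the lowest list median at 48 h, -2.27 (random lists -0.82 to 0.43), or -2.14 relative to all miRNAs, with 4 of 5 members lower. The 3 minor arms carried this value: miR-26a-1-3p was 7.61-fold lower (4.67 to 13.2), miR-26a-2-3p 7.06-fold (4.12 to 13.1) and miR-26b-3p 5.24-fold (3.24 to 9.02). Of the major arms, miR-26b-5p was 1.53-fold lower (1.51 to 1.55) and miR-26a-5p was at 4553 and 4732 RPM. The miR-15/16 family, which targets cyclin genes, had 6 of 13 members lower and 1 higher, with a median of -0.46, just below its random lists (-0.46 to 0.32), or -0.33 relative to all miRNAs, while the sum of the family, mostly miR-16-5p, was 1.08-fold higher (1.08 to 1.09). Lower members were among others the minor arm miR-16-1-3p, 4.55-fold lower (2.45 to 9.38), and miR-503-5p, 1.76-fold lower (1.61 to 1.92), while miR-497-5p was 1.60-fold higher (1.47 to 1.75). With the more abundant arms alone its median was -0.14 and lay inside the random lists.

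The remaining lists stayed inside their random ranges at 48 h; relative to the median of all miRNAs each of the following 48 h medians is greater by the shift given above. The MAPK, AP-1 and CREB linked miRNAs had 4 of 10 members lower and 1 higher and a median of -0.25: miR-21-3p was 2.56-fold lower (2.40 to 2.73), miR-221-3p 1.57-fold lower (1.55 to 1.59), which like miR-26b-5p no longer passes 1.5-fold relative to that median, miR-146a-5p 2.16-fold lower (1.27 to 3.89) and miR-132-3p 1.65-fold higher (1.40 to 1.94). At 24 h this list had 1 lower and 1 higher and a median of -0.19. With the more abundant arms alone its 48 h median was -0.07, that of the miR-30 family -0.06 and that of the miR-181 family 0.35. These lay inside their random lists. The let-7 family had 6 of 18 members lower and 0 higher and a median of -0.31, with let-7c-5p at 721.3 RPM at 0 h and 288.7 at 48 h. The miR-29 family had 3 of 7 lower and a median of -0.48, with miR-29b-3p 2.45-fold lower (2.41 to 2.48). The miR-30 family had 3 of 10 lower and a median of -0.26, with miR-30a-5p 1.71-fold lower (1.69 to 1.73). The family of miR-34 and miR-449 had 3 of 4 members higher, among them miR-34a-5p at 394.3 and 604.5 RPM, and a median of 0.60. With a floor of 1 RPM this median was 0.75 and with no floor 0.62, both outside the random lists. In the family of miR-148 and miR-152, miR-148a-3p was 2.58-fold higher (2.43 to 2.74) and miR-152-3p 1.55-fold higher (1.51 to 1.59), with a median of 0.21. That median was 0.63, outside the random lists (-0.82 to 0.52), with the more abundant arms alone, while with a floor of 1 RPM it was -0.22, inside them. Medians at 48 h were 0.09 for the miR-200 family and miR-205 (their sum was 1.16-fold lower, 1.09 to 1.24), 0.23 for the miR-23/27/24 clusters, 0.02 for the miR-99, miR-100 and miR-125 clusters, 0.09 for the miR-181 family, -0.22 for the cluster of miR-183, miR-96 and miR-182 (0.24 with the more abundant arms alone, and their sum 1.30-fold higher, 1.28 to 1.32) and 0.33 for the miR-192 family. Of the 54 list medians over the 3 times, 11 lay outside the central 95% of their random lists, where 2.70 would for lists of unrelated miRNAs. Members of the real lists often share a precursor or a cluster, and all times share the 0 h library, so 2.70 is not their chance expectation. With the more abundant arms alone 6 of 51 medians lay outside, and with a floor of 100 RPM 5 of 36.

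**Figure D1:**
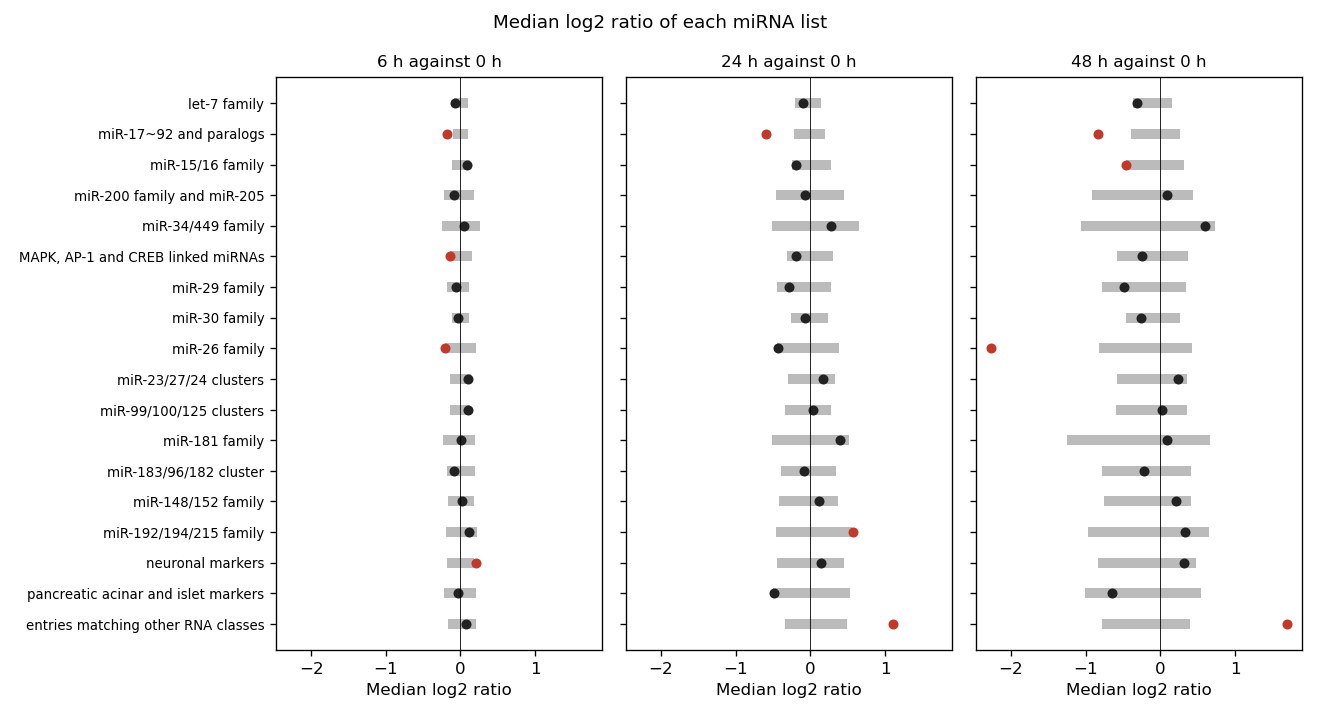
Median log2 ratio of each fixed miRNA list (x axis, log2(value + 1) at 6, 24 or 48 h minus 0 h, a panel per time, 1 library per time), with grey bars for the central 95% of 10000 abundance-matched random lists and red points for medians outside it. At 48 h the medians of the miR-26 family (-2.27), miR-17~92 and paralogs (-0.83) and miR-15/16 (-0.46) lie to the left of their bars, and that of entries matching other RNA classes (1.70) lies to the right.

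Few markers of blood cells, liver and muscle passed the floor, but 5 entries of the neuronal list and 5 of the pancreatic list did. The most abundant of these were miR-128-3p and miR-7-5p, at means of 9110 and 32383 RPM over the 4 libraries. The muscle list, the chromosome 14q32 and chromosome 19 clusters and the cluster of miR-143 and miR-145 had 0 members above the floor. Of the blood cell markers only miR-486-5p passed it, at 456.1 RPM at 0 h and 522.5 at 48 h, and the liver marker miR-122-5p was at 23.2 and 16.9. Neuronal markers had 2 of 5 members higher and 1 lower at 48 h with a median of 0.32, and miR-9-5p was 2.39-fold higher (2.16 to 2.65). The pancreatic acinar and islet markers had 4 of 5 members lower at 48 h with a median of -0.65, inside the random range (but -0.37 and outside with no floor); miR-216a-5p was 2.17-fold lower (1.81 to 2.60). The hypoxia-induced miR-210-3p was 2.09-fold higher (1.89 to 2.30) at 48 h, and the pair of miR-103a and miR-107 stayed within 1.5-fold, with miR-103a-3p at 21770 RPM at 0 h and 20703 at 48 h.

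Calls at 24 h and 48 h overlapped. Of the 46 higher at 24 h, 32 were higher at 48 h, among them miR-449a, miR-328-3p and miR-874-3p, and of the 44 lower, 39 were lower at 48 h, among them miR-222-5p, miR-29b-1-5p and miR-12135. Independent lists of these sizes would share 6.17 and 10.7. Unchanged libraries measured against the same 0 h library shared 0.449 in all with counting error alone and 1.75 with added spread, against 71 observed. Across miRNAs, which are not independent replicates, the covariance of both sets of log2 ratios was 0.66, against 0.01 and 0.03 in these simulations, and the correlation was 0.76, against 0.36 and 0.44. The single 0 h library cannot be split, so part of the excess may come from it. At 6 h, 5 of the 8 higher and 5 of the 7 lower miRNAs were called the same way at 24 h (0.987 and 0.826 in independent lists), and 3 and 7 at 48 h (1.07 and 1.71). Of the 8 higher, 1 was called lower at 24 h and 3 at 48 h. Unchanged libraries with added spread shared 1.32 with 24 h and 1.56 with 48 h in all, against 10 observed at each. That spread was estimated from the same 6 h ratios by a measure that gives little weight to their tails, where the calls lie. The 10 shared calls are therefore described and not tested by it.

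**Figure D2:**
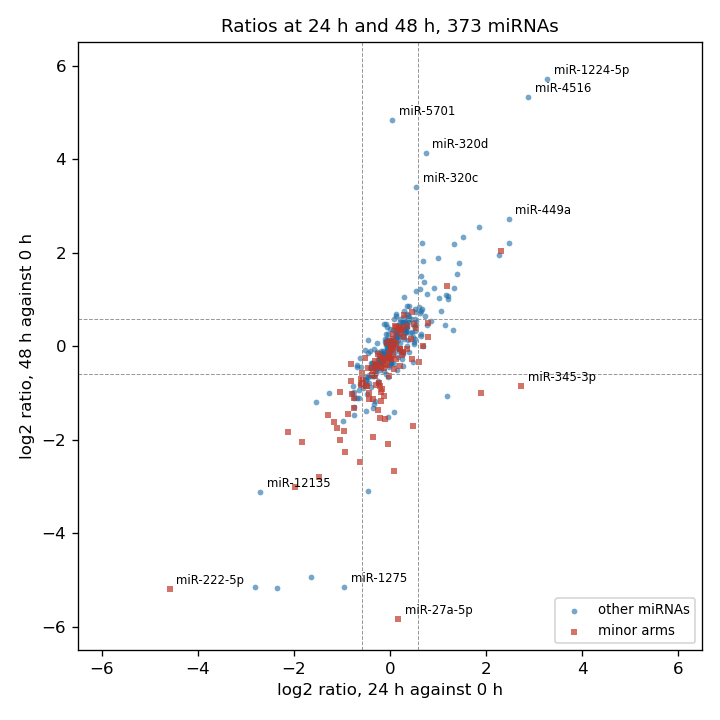
Log2 ratio at 24 h (x axis) against that at 48 h (y axis), both on the log2(value + 1) scale against the same 0 h library, for 373 miRNAs with 1 library per time; red squares are minor arms with a more abundant partner arm, blue points are all other miRNAs, and dashed lines mark 1.5-fold. Most points past the lines at both times lie in the lower left or upper right, while miR-345-3p (2.74 and -0.85) and miR-27a-5p (0.17 and -5.83) lie apart.

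Levels were in strict order over time in more miRNAs than an exchangeable order would give. Of the 373, 47 were strictly rising over 0, 6, 24 and 48 h and 76 strictly falling, where 15.5 of each would be for exchangeable values. Those in falling order included miR-222-5p, miR-29b-1-5p, miR-26a-1-3p, miR-20a-5p and miR-18a-5p, and those in rising order miR-449a, miR-328-3p, miR-874-3p and miR-7977. Without the 48 h library 96 were rising and 99 falling over 0, 6 and 24 h, where 62.2 of each would be for exchangeable values. Sequencing depth also fell in the order of time, and a graded technical difference could order many miRNAs together. Members of a precursor or cluster are not independent either. The exchangeable shares are therefore no chance expectation, and the cause of the order was not tested. By step, 8 miRNAs were higher and 7 lower at 6 h than at 0 h, 41 and 28 at 24 h than at 6 h, and 17 and 54 at 48 h than at 24 h. Among the 77 miRNAs above 1000 RPM, 0, 5 and 14 were called at 6, 24 and 48 h, the 14 including miR-301a-3p and miR-339-5p, which were higher, and miR-29b-3p and miR-30a-5p, which were lower.

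**Figure D3:**
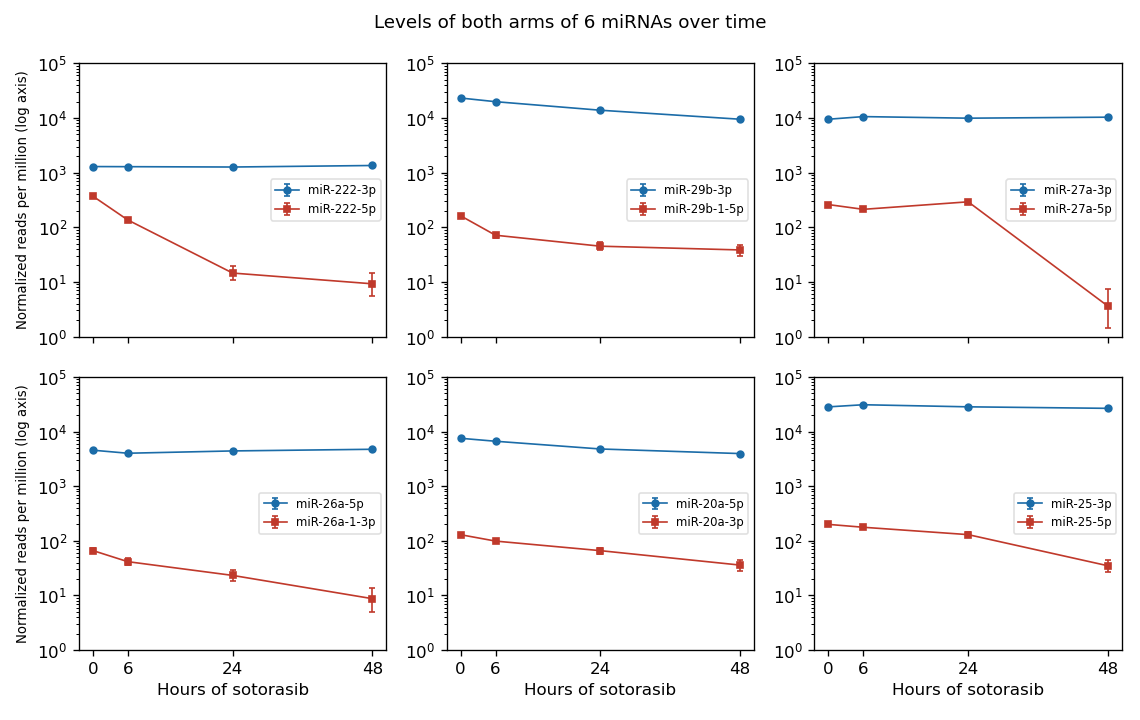
Normalized reads-per-million (y axis, log axis) at 0, 6, 24 and 48 h of sotorasib (x axis) for both arms of 6 miRNAs, 1 library per time, with the more abundant arm in blue, the other in red, and bars for exact 95% counting intervals. The 6 pairs were picked outside the fixed rule, and the minor arm of each was lower at 48 h. Of all 113 pairs, the minor arm had the lower log2 ratio in 82 at 48 h. The level of miR-222-5p goes from 372.2 to 9.23 while miR-222-3p goes from 1292 to 1351, and miR-27a-5p drops between 24 h (292.4) and 48 h (3.59) while miR-27a-3p is at 9923 and 10351.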

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

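The test of the 48 h library's preparation was chosen after the result was seen. A group of 5 miRNAs was called in opposite directions at different times; these differences were not tested, since each time has 1 library. The log2 ratio of miR-345-3p against 0 h was 0.72 at 6 h, 2.74 at 24 h and -0.85 at 48 h. That of miR-195-3p was 1.90 at 24 h and -1.01 at 48 h, and that of miR-1260a, an entry that also matches a tRNA, was 1.19 at 24 h and -1.06 at 48 h. That of miR-1275 was 0.63 at 6 h, -0.96 at 24 h and -5.15 at 48 h, and that of miR-128-1-5p was 0.61 at 6 h and -1.94 at 48 h. The 48 h values of miR-345-3p and miR-1275 rest on 8 and 3 reads.

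Of these 5, 4 belong to a group of 12 miRNAs at least 4-fold lower at 48 h than at 24 h, the others being miR-27a-5p, miR-3662, miR-573, miR-26a-2-3p, miR-1268a, miR-7974, miR-181b-2-3p and miR-23a-5p; 6 of the 12 are minor arms. Random loss of reads at the 48 h depth is argued against, since 100 thinnings of the 24 h library to that depth gave at most 0 such miRNAs. Each thinning was compared with the same 24 h library, so only counting error was covered. A 48 h library made from fewer molecules stays open. A quadratic trend with GC content explained 0.803% of the variance of this step, and 83.3% of the 12 stayed 4-fold lower after it was subtracted (miR-181b-2-3p and miR-23a-5p, at -2.18 and -2.04 before, did not), so such a smooth trend is argued against as the whole cause. It spanned only -0.23 to 0.21, and the median GC content of the 12 was 57.3% against 49.1% for all miRNAs (for 6 of the 12 over the whole precursor), so another effect of GC content on these miRNAs stays open. Preparation of the 48 h library alone cannot be told apart from the time of treatment: 4 of the 12 were already lower at 24 h in another library, and the other 8 were not. A late effect of the treatment or of time in culture is an untested hypothesis, and replicate 48 h libraries with and without treatment would be needed.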

How the results depend on the processing

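Thinning, leaving out entries that match other RNA classes, and ordering without the 48 h library were chosen after seeing the data. No call of a named miRNA and no list median outside its random lists changed sign. Counts of called miRNAs stayed within 1.5 times the reported ones under every other scaling, the authors' ratios and a pseudocount of 0.1. Of 102 calls of named miRNAs, 102 were kept with the authors' ratios, 99 when centred on the median, 98 by total reads, 98 by median-of-ratios, 86 with a pseudocount of 10 and 95 after thinning. Floors mattered most, because they change which miRNAs are compared. With a floor of 1 RPM the counts higher and lower were 41 and 46 at 6 h, 104 and 115 at 24 h and 106 and 187 at 48 h, with 140 shared by 24 h and 48 h. With a floor of 100 RPM they were 0 and 3, 14 and 18, and 22 and 38, with 30 shared, 80 in strict order and 5 list medians outside their random lists (11 reported). With no floor they were 79 and 100, 153 and 174, and 216 and 238, with 198 shared. A 2-fold rule gave 0 and 2, 24 and 16, and 30 and 51, with 32 shared, as a stricter rule must give fewer. A pseudocount of 10 left 1 higher at 6 h, as it shrinks the ratios of low miRNAs. Thinning to the 48 h depth, a single random draw, gave 12 higher and 13 lower at 6 h, as drawing fewer reads adds counting error. Order over 0, 6 and 24 h alone held for 195, as fewer times are easier to order. With the more abundant arms alone 6 list medians lay outside: miR-17~92 and paralogs at 6, 24 and 48 h, entries matching other RNA classes at 24 and 48 h, and the family of miR-148 and miR-152 at 48 h. Of the 54 list medians, 13 changed sign in some alternative, all inside their random lists as reported. Those at 48 h were the miR-200 family with miR-205 (0.09, but -0.26 with a floor of 1 RPM), the miR-99, miR-100 and miR-125 clusters (0.02, -0.15), the family of miR-148 and miR-152 (0.21, -0.22), the miR-181 family (0.09, but -0.17 with no floor) and the cluster of miR-183, miR-96 and miR-182 (-0.22, but 0.24 with the more abundant arms alone or a floor of 100 RPM). Some outside medians came inside: the neuronal list at 6 h with every other floor, a pseudocount of 10 and thinning, the MAPK list at 6 h with floors of 1 and 100 RPM and thinning, the miR-26 family at 6 h with no floor, the miR-192 family at 24 h with a pseudocount of 10 and thinning, and miR-15/16 at 48 h with a floor of 100 RPM and thinning. Others came outside: the family of miR-34 and miR-449 at 48 h with a floor of 1 RPM (0.75) and at 24 and 48 h with no floor (0.30, 0.62), the miR-200 family with miR-205 at 6 h (-0.29) and the pancreatic list at 48 h (-0.37) with no floor, the family of miR-148 and miR-152 at 24 and 48 h with a floor of 100 RPM (0.40, 0.63), the miR-26 family at 24 h with a pseudocount of 10 (-0.43) and the pancreatic list at 24 h after thinning (-0.67). All 90 calls at 24 h and 140 of the 141 at 48 h were kept when calls with a counting interval that includes 1 were left out. Calls with a miRNA listed at 0 have no such interval and were kept without this check. No paired analysis was possible because each time has 1 library and no test was run. Depth limits the 48 h library most: a miRNA at 10 RPM has about 19.5 reads there and 44.0 at 0 h.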

Other observations

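The tests of the 48 h library's preparation and of reads moved between miR-320 members were chosen after the result was seen. From the chromosome 7 cluster (MIR29A at 130876747 to 130876810 and MIR29B1 at 130877459 to 130877539), miR-29b-1-5p was 4.23-fold lower at 48 h (3.33 to 5.43) and miR-29a-5p 3.09-fold lower (2.51 to 3.85), while the abundant miR-29a-3p was 1.40-fold lower (1.39 to 1.41), within 1.5-fold. From the chromosome 1 cluster (MIR29C at 207801852 to 207801939 and MIR29B2 at 207802443 to 207802523, both in exons of MIR29B2CHG), miR-29b-2-5p was at 16.1 RPM at 0 h and 22.0 at 48 h, and miR-29c-3p was 1.30-fold higher (1.26 to 1.34), within 1.5-fold. The shared arm miR-29b-3p, which both clusters encode, was 2.45-fold lower (2.41 to 2.48). A difference between the clusters was not tested.

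Other members of the miR-449 cluster lay below the abundance floor: at 0, 6, 24 and 48 h miR-449b-5p was at 0, 1.17, 2.62 and 14.4 RPM, and miR-449c-5p at 2.5, 6.57, 16.6 and 14.4. Both arms of the miR-874 precursor, in an intron of KLHL3, were higher at 48 h, miR-874-3p 4.68-fold (3.70 to 5.94) and miR-874-5p 4.59-fold (2.87 to 7.50). In the chromosome 19 cluster of MIR23A and MIR27A, the minor arms miR-23a-5p and miR-27a-5p were 5.50-fold (2.23 to 17.5) and 72.6-fold lower (35.1 to 181), while miR-23a-3p and miR-27a-3p were within 1.5-fold, with log2 ratios of 0.30 and 0.12. The 3 genes MIR26A1, MIR26A2 and MIR26B, whose minor arms were all lower at 48 h, lie in introns of CTDSPL, CTDSP2 and CTDSP1.

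Minor arms were lower relative to their partners as treatment went on: over 113 pairs the median log2 difference, minor minus major arm, was -0.01 at 6 h, -0.13 at 24 h and -0.38 at 48 h, and 47 of 113 minor arms but 15 of 108 major arms were called lower at 48 h. The minor arm had the lower ratio in 82 of the 113 pairs at 48 h, and the rest went the other way. Low abundance is argued against, since the minor arms' median of -0.42 at 48 h lay below abundance-matched lists of other miRNAs (-0.13 to 0.14). A straight-line trend with the GC content of the precursor sides is argued against as the whole cause. The fitted within-pair difference at equal GC was -0.62 (bootstrap interval -0.83 to -0.42). This is a least-squares value, which extreme pairs can pull, so it is not to be set beside the medians. The GC content of the mature arms themselves was not used, and another effect of GC content stays open. In 100 random thinnings to the 48 h depth the median difference was -0.49 to -0.32. Such thinning covers counting error only and keeps the expected levels, so it cannot decide whether the shallow 48 h library is the cause. A 48 h library made from fewer molecules stays open. Preparation of the 48 h library alone cannot be told apart from the treatment, since the difference of -0.13 at 24 h is too small to decide. Without untreated libraries at the later times, treatment and time in culture cannot be told apart either. An effect of the treatment or of time in culture on the arms stays open as an untested hypothesis.

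While miR-320c and miR-320d were higher at 48 h, miR-320a-3p was at 1412 RPM at 0 h and 1542 at 48 h. Reads moved between miR-320 members are argued against as the whole cause, since the sum of the 5 members was 1.91-fold higher (1.85 to 1.98). A quadratic trend with GC content (taken over the whole precursor for miR-320c and miR-320d) explained 2.58% of the variance of the 48 h ratios. Such a smooth trend is argued against as the whole cause, since the smaller of both log2 ratios was 3.70 after it was subtracted. The trend spanned only -0.29 to 0.89, so subtracting it could not bring these ratios to 1.5-fold, and another effect of GC content stays open. Fragments of another transcript, and a difference in the preparation of the 48 h library, may also give such reads and stay open. Effects of the treatment and of time in culture are untested and stay open too.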
